A study of Homo sapiens with 8 samples.

How the data were processed

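Skin of 4 people with atopic dermatitis (AD) and healthy skin from the surgical margins of 4 Mohs patients was profiled by RNA sequencing. Per the labels, total RNA from biopsies was depleted of ribosomal RNA, copied with random hexamers and read as single reads of 50 bases on an Illumina HiSeq. The deposited files hold raw read counts per Ensembl gene, without normalization, which the authors made with STAR 2.0.4b and Subread featureCounts 1.4.5 on GRCh38. The strand setting, the treatment of reads that map to several places and the annotation release are not stated. Values of close paralogs and of genes with exons on opposite strands are uncertain for that reason.

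Each file held 62562 entries for 62120 Ensembl genes. The 442 repeats had identical counts, and 1 was kept per gene. Coordinates and gene types came from GENCODE release 29, which lists 55298 of these genes, and 0.32% of counts fell outside it. In 29 entries the gene name was stored as a date, and these genes were not named. Total counts per library ran from 8.64 to 14.8 M. A gene with 3 counts in a library corresponds to 0.203 to 0.355 CPM, on totals scaled by the factors below.

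The groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, with robust estimation, factors from the trimmed mean of M values (TMM) and filterByExpr defaults (minimum count 10, minimum total 15). The design had the group alone, because nothing pairs the donors. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Log2 changes are AD minus margin. Their standard error (SE) was derived from the test, as the absolute log2 change divided by the square root of the F statistic. CPM values are means ± SD over the 4 libraries of a group. The biological coefficient of variation was 34.3%. On simulated data of this size the test called 71% of genes changed 4-fold and 8.57% of genes changed 2-fold, and 4.60% of calls were unchanged genes. Few simulated genes were changed and each gene was drawn independently, so these shares need not hold for the real data. Ratios of low counts carry exact Clopper-Pearson intervals at 95%. The reads of a group are pooled for them, so they cover counting error only and not differences between donors.

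A total of 35 gene lists with 633 members was fixed before the data were examined, along with the tests, the alternatives and the rule for naming genes. All 633 members were matched, 7 of them through a newer symbol. The lists covered keratinocyte states, proliferation, barrier lipids, cytokine axes, leukocytes, skin appendages, other dermal cells, muscle, fat, itch, Hedgehog, clock, immediate early, HOX, mitochondrial and red blood cell genes. Lists with at least 5 tested members, 33 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera was also run with the correlation estimated per list, and fry was run on each list. Members were counted past the threshold over all genes and when adjusted over the list alone. List scores are the mean log2 CPM of a list's tested members, with a prior count of 2.

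The named genes were the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap and whose higher group averaged at least 1 CPM. Up to 3 called members per list were added, or the member with the highest CPM where none was called. FLG, LOR, IL13, IL4R, CCL17, CCL26, S100A7, KRT16, IL31RA and TSLP were always named. For 1 list the member that met this rule is not reported. Genes named outside this rule illustrate a list or family. The desmosome, NR4A and dual oxidase sets and the family counts of keratins, keratin-associated proteins and histones were chosen after their values were seen. Genes that show the sex or a common genotype of a donor were left out of naming and of values per library.

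The alternatives were DESeq2 size factors (RLE), library size alone and upper-quartile factors for scaling, no count filter, a filter of 1 CPM in 4 libraries, protein-coding genes alone, estimation without robustness, limma-voom with quality weights, 1 surrogate variable from sva 3.50.0, DESeq2 1.42.0 and each library left out in turn. Added after the data were seen were fits without margin libraries 3 and 4, without those and AD library 3, and with the sebaceous list score as a covariate. The test was repeated on all 35 splits of the 8 libraries into groups of 4. A library was set apart from its group of 4 when its gap to the next, over the range, exceeded Dixon's 0.829. Exact permutation tests used SciPy 1.17.1 in Python 3.11.15 and were two-sided. They include a test of each list score over the 70 assignments of 4 of 8 libraries, added after the data were seen.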

Results

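RNA was sequenced from skin biopsies of 4 people with atopic dermatitis (AD) and from 4 pieces of uninvolved skin at the edge of Mohs surgery, an excision used for skin cancer. Each library came from a separate donor, so the comparison between groups is unpaired. The AD libraries 1 to 4 held 13.3, 13.7, 12.6 and 10.04 M counted reads. The margin libraries 1 to 4 held 10.5, 8.64, 14.8 and 11.03 M. The first principal component of log2 CPM (read counts scaled to the library total) held 35.8% of the variance and separated the groups, and the second held 20.4%.

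The comparison asks how gene expression in AD skin differs from that in uninvolved surgical-margin skin. Of 19337 genes tested, 367 were higher and 363 were lower in AD by the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. All 4 AD libraries lay above all 4 margin libraries for 366 of the 367, and below them for 359 of the 363. Among all tested genes 14.5% separated the groups in this way, against 2.86% expected for a single gene by chance. Genes vary together, so the share over all genes can lie far from that value by chance, and the gap is no test. At an unadjusted p under 0.05 there were 4442 genes. Scaling by library size alone moved the median log2 change of all genes by −0.20 and gave 223 higher and 744 lower.

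The count of changed genes fell in each fit with 1 library left out, by an amount that depended on the library. Fewer samples also lower the power of these fits. The count was 68 without AD library 2, of which 25 were higher, and 86 without margin library 4, of which 24 were higher. Counts of list members past the threshold in these fits, given below, are to be read against this fall over all genes. It was 150 and 192 without AD libraries 4 and 3, and 286 without margin library 2. Without AD library 1 there were 405 higher and 210 lower, and without margin library 1 there were 226 higher and 330 lower. Leaving out margin library 3 gave 274 higher and 290 lower. All 39 named genes past the threshold kept their sign in every setting, while KRT14, KRT6A, MITF and KRTAP19-1 alone kept the threshold in each fit without 1 library that tested them. With all libraries kept, 19 of the 39 lost the call in at least 1 planned setting. Without a count filter these were AKR1B15, ALOX12B, DPT, KRT15, KRT16, KRT6B, KRT6C, KRTAP4-2, KRTAP4-3, KRTAP7-1, KRTAP8-1, SH2D5, SLC5A5 and SLN. With 1 surrogate variable they were ALOX12B, CTGF, DPT, IL1B, IL4R, KRT15, KRT16, KRT6C and KRTAP4-2. With limma-voom they were KRTAP4-2, KRTAP4-3, SH2D5, SLC5A5 and SLN. SLN lost it with RLE factors, IL4R and TPX2 with library size alone, and SCN7A with upper-quartile factors.

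**Figure D1:**
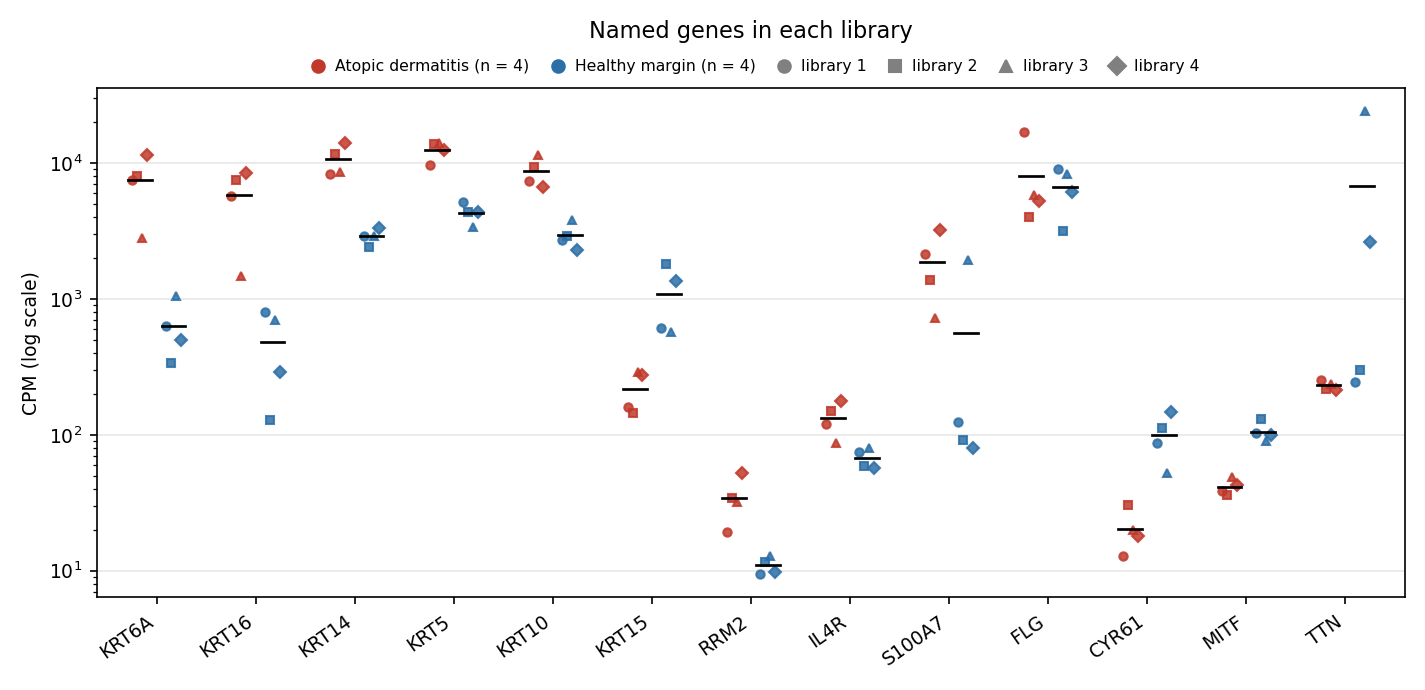
CPM on a log axis for 13 named genes in each library, with red for AD, blue for margin skin, a marker shape per library number and a black line at the group mean (n = 4 per group). KRT6A, KRT14 and RRM2 separate the groups, whereas FLG overlaps and TTN is high in margin libraries 3 and 4.

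Keratins of activated epidermis were among the genes with the largest rise. KRT6A (ENSG00000205420, chromosome 12, 52487174 to 52493257 on GRCh38) had 7477 ± 3559 CPM in AD and 633 ± 310 in margin skin (mean ± SD, n = 4 each). Its log2 change was 3.56 (SE 0.50, adjusted p = 0.0164). KRT16 changed by 3.59 (SE 0.70, adjusted p = 0.0311), KRT6B by 2.59 (SE 0.50) and KRT6C by 4.80 (SE 0.92). These 3 did not pass without a count filter, nor did KRT16 and KRT6C with 1 surrogate variable. KRT6A, KRT6B and KRT6C are near copies, as are KRT16 and KRT14, so the split of short reads among them is uncertain. KRT6A, KRT16, KRT6B and KRT6C were the members of the activated keratinocyte list that rose, of 24 tested, and 14 rose when adjusted over the list alone. The number that rose was 10 without margin library 3, 2 without AD library 1, and 1 without AD library 2, AD library 4, margin library 2 or margin library 4. The list's median log2 change was 2.04, with an adjusted p of 3.27e-12 by camera at its preset correlation and 0.644 with an estimated correlation. SPRR1A (2.35), SPRR1B (2.19) and LCE3D (3.61) did not pass over all genes.

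Structural keratins rose as well. KRT14 (ENSG00000186847, chromosome 17, 41582279 to 41586921) went from 2904 ± 379 to 10730 ± 2730 CPM, a log2 change of 1.89 (SE 0.25, adjusted p = 0.0164). KRT5 rose by 1.53 (SE 0.23), KRT10 by 1.58 (SE 0.26) and KRT1 by 1.17 (SE 0.27). KRT15 fell by 2.32 (SE 0.42). Among 14 basal keratinocyte and basement membrane genes 4 rose, KRT14, KRT5, ITGA3 (1.20) and ITGB4 (1.14), and 1 fell. Adjusted over the list alone, 7 rose and 1 fell. The number that rose was 1 without AD library 2 or margin library 4, and 2 without AD library 3, AD library 4, margin library 2 or margin library 3. KRT15 did not pass without AD library 2, 3 or 4, or margin library 4. The median was 0.65, with an adjusted p of 0.000246 by camera and 0.644 with an estimated correlation.

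Of 33 genes of terminal differentiation and the cornified envelope 6 rose: KRT10, KPRP (1.99, SE 0.35), DSG1 (1.26, SE 0.26), TGM3 (2.28), KRT1 and DSC1. Adjusted over the list alone, 10 rose and 2 fell, LCE5A (−2.67) and CST6 (−1.68). The count that rose was 0 without AD library 2 or margin library 4, 1 without AD library 3 or 4, and 3 without AD library 1 or margin library 2. The median was 1.08, with an adjusted p of 5.06e-07 by camera and 0.776 with an estimated correlation. Margin library 2 had the lowest score of this list, and without it the median was 0.73 and the difference of the group scores went from 0.91 to 0.47. FLG, which encodes filaggrin, had 8011 ± 6001 CPM in AD and 6667 ± 2646 in margin skin, a log2 change of 0.27 (SE 0.49, adjusted p = 0.801). Loricrin (LOR) changed by 0.14 (SE 0.41, adjusted p = 0.883). ALOX12B, of the epidermal lipid list, rose by 1.76 (SE 0.38) and was the only one of 22 members to pass, with 4 when adjusted over the list alone. That list had a median of 0.42, a mean of 0.00 and a camera adjusted p of 0.0365 (0.811 with an estimated correlation), and camera called it in 5 of the 8 fits with 1 library left out. Among the fits with 1 library left out, ALOX12B passed without margin library 3 alone.

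In a set of 18 desmosome and cornified junction genes, drawn up after the values were seen, 12 rose and 1 fell. Cadherin genes as a family had 9 of 14 negative and a median of −0.53. Of these 14, 2 rose, CDH1 and CDH3, which are also in the set, and 1 fell. No test compared the family with the set. JUP rose by 1.57 (SE 0.23), PKP1 by 1.47 (SE 0.21), DSG3 by 1.53 (SE 0.29) and CDH3 by 1.66 (SE 0.31), and DSG2 fell by 0.81 (SE 0.17). PKP4, at 0.14, changed sign under library-size scaling. The number that rose was 0 without AD library 2 or margin library 4, and 5 to 7 without AD library 3 or 4, or margin library 1, 2 or 3. Over the set alone 14 rose in each of these fits. The set was drawn up from these same values, so counts over the set alone give no support to the rise. DUOX1 (1.72, SE 0.22) and DUOXA1 (1.59, SE 0.26), also singled out afterwards, encode an epithelial oxidase and its maturation factor. They rose, with 1 of the pair past the threshold without AD library 2, AD library 4 or margin library 4, while the neighbouring DUOX2 (0.68, SE 0.29, adjusted p = 0.196) and DUOXA2 (0.28, SE 0.31, adjusted p = 0.642) did not pass.

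All 22 proliferation genes had a positive log2 change, with a median of 1.03. RRM2 rose by 1.65 (SE 0.28, adjusted p = 0.0239), from 10.9 ± 1.63 to 34.3 ± 13.6 CPM. BIRC5 rose by 1.44 (SE 0.29), TPX2 by 1.22 (SE 0.26), MKI67 by 1.24 and CCNA2 by 1.19. These 5 passed over all genes and 20 adjusted over the list alone. Over all genes 13 passed without AD library 1, 2 without margin library 3, 1 without AD library 3, AD library 4, margin library 1 or margin library 2, and 0 without AD library 2 or margin library 4, while the count over the list alone stayed between 16 and 21. The camera adjusted p was 9.69e-14, and 0.644 with an estimated correlation. Of 56 histone genes tested 55 had a positive log2 change, and 5 rose, such as HIST1H2AB (1.65, SE 0.32). That number was 11 without AD library 1, 1 without margin library 3 and 0 in each other fit with 1 library left out.

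Genes of the type 2 immune axis gave few calls, and 13 of the 21 list members were tested. IL4R rose by 0.99 (SE 0.23, adjusted p = 0.0456), from 67.4 ± 11.4 to 134 ± 38.9 CPM, and passed without AD library 3 but in no other fit with 1 library left out. It was 1 of 13 list members to pass, over all genes and over the list alone. The list's median was 0.61, with an adjusted p of 0.0491 by camera and 0.811 with an estimated correlation. AD library 3 had the lowest score of its group, and without it the median was 0.76 and the difference of the group scores went from 0.45 to 0.80. The median was 0.32 without AD library 2 and 0.35 without AD library 4, and camera called the list in 2 of the 8 fits with 1 library left out. CCL17 changed by 0.63 (SE 0.74, adjusted p = 0.662) and TSLP by 0.99 (SE 0.49, adjusted p = 0.265). IL13, with 40 counts over the 4 AD libraries and 23 over the margin libraries, and CCL26, with 51 and 13, were below the count filter. With no filter their log2 changes were 0.87 and 2.09, with adjusted p values of 0.525 and 0.0661. CCL18 and IL31, also on this list, had 0 counts in AD and 0 in margin skin. Whether their transcripts were absent or their reads were lost in counting was not tested. IL31RA, part of the interleukin-31 receptor, changed by −0.79 (SE 0.69, adjusted p = 0.541). HRH1, a histamine receptor, rose by 1.71 (SE 0.34) and was the only one of 15 tested itch genes to pass. OSM, an itch gene below the filter with 25 counts in AD and 121 in margin skin, had a log2 change of −2.27 with no filter and an adjusted p of 0.0158. HRH1 did so without AD library 1 or 3 but in no other such fit, and that list's median was −0.09, with 1 member up and 1 down over the list alone.

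S100A7 had 1870 ± 1077 CPM in AD and 559 ± 920 in margin skin, a log2 change of 1.74 (SE 1.13, adjusted p = 0.404), with margin library 3 at the level of AD. S100A9 changed by 1.71 (SE 1.24, adjusted p = 0.460). None of 13 tested genes of the interleukin-17 and interleukin-22 axis passed, and 1 fell over the list alone, with a median of 0.65. IL22 had 38 counts in AD and 5 in margin skin (AD to margin ratio 7.80, 95% exact interval 3.06 to 25.4) and was below the count filter. That interval covers counting error only and leaves out differences between donors. With no filter IL22 had a log2 change of 2.89, with an adjusted p of 0.0396. In the interleukin-1 family IL1B fell by 1.74 (SE 0.38), from 6.58 ± 2.28 to 1.95 ± 0.87 CPM, and passed without AD library 1 or margin library 3 only. IL36A (2.63) and IL36G (1.77) did not pass. Of the 13 tested members 1 rose and 2 fell over the list alone, and the median was 0.84. This median was 0.40 without AD library 4 and 0.96 without margin library 3. The type I interferon list had 15 of 19 members positive, a median of 0.65 and no member past the threshold, although 5 rose over the list alone without AD library 3. Its camera adjusted p was 0.0354, and 0.811 with an estimated correlation. The median was 0.03 without AD library 2 and 0.96 without AD library 3, and camera called this list in 4 of the 8 fits with 1 library left out. None of 13 genes of the interferon-gamma list passed, and its median was 0.13.

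Among leukocyte markers CXCR1 alone passed. No member passed among 19 T cell genes (median 0.09, mean 0.04, though ranked downward by camera), 9 natural killer genes (−0.04), 14 Langerhans and dendritic cell genes (0.24) or 13 mast cell genes (−0.46). The Langerhans and dendritic cell median was 0.0082 without AD library 1 and 0.59 without AD library 3, the only such fit in which camera called that list. The mast cell median was −0.81 without AD library 4 and −0.19 without AD library 3. Camera called the mast cell list in 3 of the 8 fits with 1 library left out. CD4 changed by −0.50 (SE 0.39), CD207 by −0.78 (SE 0.58), KIT by 0.12 (SE 0.20) and NCAM1 by −1.92 (SE 0.59). All 14 macrophage genes had a negative value and none passed. Their median was −0.98, with F13A1 at −0.67, and the camera adjusted p was 0.00495, or 0.811 with an estimated correlation. AD library 3 had the lowest macrophage score, and without it the difference of the group scores went from −0.84 to −0.42 and the median was −0.71. The median was −0.43 without margin library 1, and camera did not call the list in either of these fits. Just 3 B cell and plasma cell genes were tested (median 0.01), with IGKC at 0.73 (SE 1.16). CXCR1, a neutrophil receptor, rose by 3.60 (SE 0.67), from 0.26 ± 0.13 to 3.37 ± 2.31 CPM, while the median of the 6 neutrophil and eosinophil genes was −0.77, and 1 of them rose and 1 fell over the list alone. CXCR1 passed without AD library 1, margin library 1 or margin library 3 and was below the count filter without AD library 2 or 3.

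**Figure D2:**
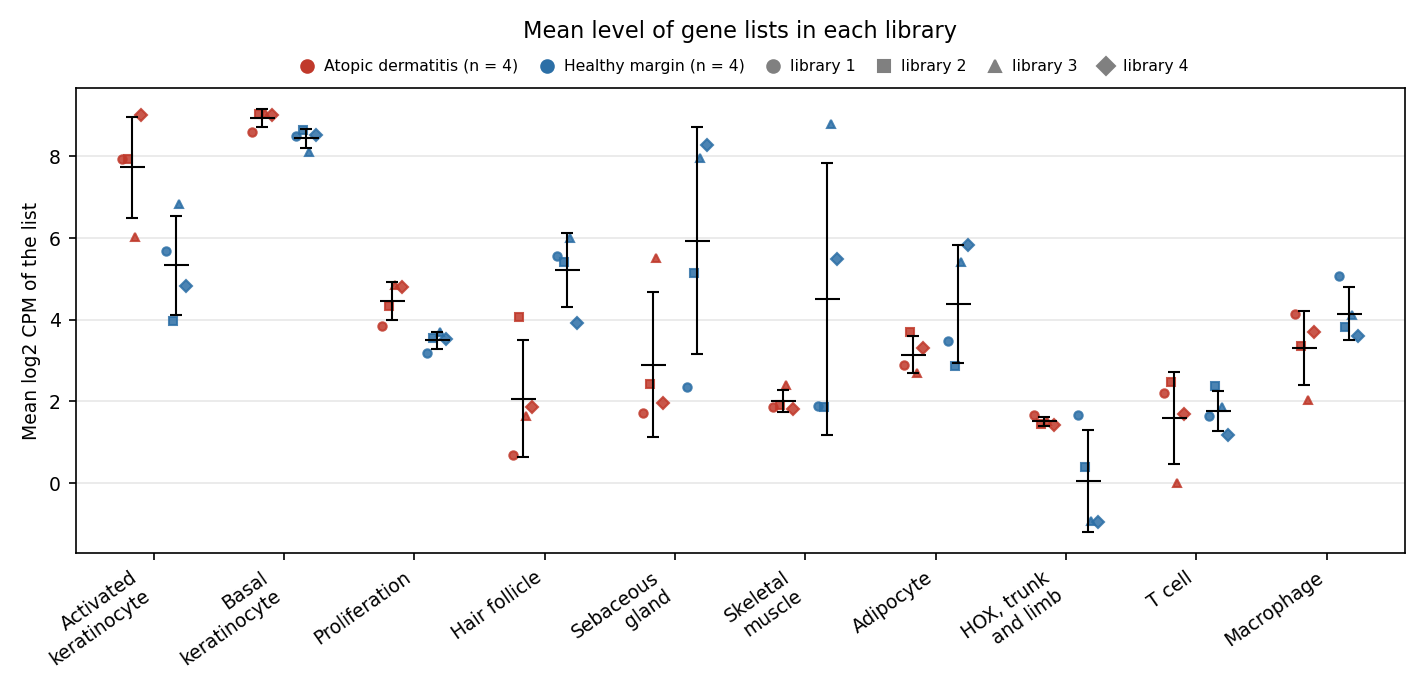
Mean log2 CPM of the tested members of 10 gene lists in each library, with red for AD, blue for margin skin, a marker shape per library number, and bars for the group mean ± SD (n = 4 per group). Skeletal muscle scores are 8.78 and 5.49 in margin libraries 3 and 4 and lie between 1.82 and 2.41 elsewhere.

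Hair shaft genes were lower in AD. The log2 change was −8.28 (SE 1.46) for KRTAP7-1, −7.16 (SE 0.87) for KRTAP19-5, −6.42 (SE 1.39) for KRTAP4-2 and −6.39 (SE 0.99) for KRTAP8-1. It was −6.29 (SE 1.05) for KRTAP19-3, −6.28 (SE 0.86) for KRTAP19-1 and −6.07 (SE 1.15) for KRTAP4-3. KRTAP7-1 had 1 count over the AD libraries and 522 over the margin libraries, a margin to AD ratio of 509 (95% exact interval 91.0 to 20140). The ratio was 230 (40.9 to 9127) for KRTAP19-5, 107 (29.3 to 891) for KRTAP19-3, 98.5 (33.4 to 480) for KRTAP19-1 and 98.6 (47.6 to 246) for KRTAP8-1. Margin library 3 held 325 of the 522 margin counts of KRTAP7-1. Without this library the ratio was 279 (49.5 to 11080) for KRTAP7-1, 137 (24.1 to 5482) for KRTAP19-5, 50.3 (13.4 to 423) for KRTAP19-3, 58.5 (19.6 to 288) for KRTAP19-1 and 50.6 (24.2 to 127) for KRTAP8-1. These intervals cover counting error only. All 22 tested keratin-associated protein genes had a negative change and 15 fell, a count reaching 1 of 29 without AD library 2, 2 without AD library 3 or 4, 5 without AD library 1, 8 without margin library 1 and 9 without margin library 2. In the hair follicle list 0 of 21 genes passed over all genes and 16 fell over the list alone, or 0 without AD library 4. Without AD library 2, which had the highest hair score of its group, 6 fell over all genes. Its median was −3.14, with TCHH at −2.35 (SE 1.34), and the camera adjusted p was 1.36e-10, or 0.644 with an estimated correlation.

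Muscle, fat and sebaceous genes were highest in margin libraries 3 and 4. TTN had 231 ± 18.6 CPM in AD and 6804 ± 11560 in margin skin, a log2 change of −4.88 (SE 1.498, adjusted p = 0.105), with its high values in margin libraries 3 and 4. SLN, a muscle gene, fell by 6.90 (SE 1.55), with 6 counts in AD and 938 in margin skin (ratio 152, 69.8 to 416). Margin library 3 held 814 of the 938, and without it the ratio was 29.3 (13.1 to 81.3). Both intervals cover counting error only. SLN passed without margin library 1 or 3 but in no other such fit. None of 16 skeletal muscle genes passed and 14 fell over the list alone, with a median of −5.08; over the list alone 0 fell without any 1 AD library or without margin library 3. The median was −3.13 for 19 sebaceous gland genes, with FADS2 at −3.04 (SE 1.71), and −1.77 for 14 adipocyte genes, with CD36 at −0.23 (SE 0.53). No member of either list passed, over all genes or over the list alone. Without AD library 3, which had the highest sebaceous score of its group, 18 sebaceous genes fell over the list alone, and without margin library 1 there were 13. Without margin library 1 or 2, 6 or 10 adipocyte genes fell over the list alone. The median was −2.18 for muscle without margin library 3, −1.16 for fat without margin library 4 and −5.95 for sebaceous gland without AD library 3. Camera gave adjusted p values of 0.000414, 7.25e-06 and 0.000907 for muscle, sebaceous gland and fat, and 0.811 for each with an estimated correlation. Sweat gland genes had a median of 0.43, with DCD at 1.48 (SE 1.07). That median ran from 0.23 to 1.05 with 1 library left out.

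HOX genes of the trunk and limb, whose expression follows body site, had a median of 0.74 over 19 members and none passed (camera adjusted p = 0.000403, or 0.811 with an estimated correlation). Their mean log2 CPM was 1.67, 0.39, −0.93 and −0.94 in margin libraries 1 to 4 and between 1.43 and 1.67 in AD. Without margin library 1, 8 HOX genes rose and the median was 2.24. It was 0.39 without margin library 3 and negative without margin libraries 3 and 4. HOXD8 changed by −0.80 (SE 0.31, adjusted p = 0.163). The body sites are not given in the labels.

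Several early response genes were lower in AD than in margin skin. The design confounds disease with the surgical origin of the margin skin, so a fall in AD cannot be told from a rise in the margin. CYR61 (ENSG00000142871, chromosome 1, 85580761 to 85583962) went from 99.7 ± 39.8 to 20.3 ± 7.25 CPM, a log2 change of −2.30 (SE 0.35, adjusted p = 0.0180). CTGF fell by 1.73 (SE 0.33) and EGR1 by 0.93 (SE 0.17). EGR2 fell as well, and NR4A1 by 2.59 (SE 0.51). These 5 of 18 immediate early and stress genes fell and 6 did over the list alone, while FOS (−0.12), JUN (0.08) and JUNB (0.00) did not pass. The list's median was −0.12, its camera adjusted p was 0.0317, and it was 0.811 with an estimated correlation. Camera called it in 4 of the 8 fits with 1 library left out. The number that fell was 0 without AD library 4, 1 without AD library 2 or margin library 4, and 2 without AD library 3 or margin library 2. NR4A2 (−3.17, SE 0.59) and NR4A3 (−3.16, SE 0.52), chosen after their values were seen, fell with NR4A1, and 0 of these 3 passed without AD library 4 or margin library 4, with 1 passing without AD library 2, AD library 3 or margin library 2.

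All 10 Hedgehog pathway genes had a negative change, with a median of −1.19. HHIP fell by 1.85 (SE 0.35), from 3.77 ± 1.34 to 1.04 ± 0.27 CPM, and GLI1 (−1.58) did not pass. Over the list alone 5 fell, 3 without AD library 1 or 4 and 1 without margin library 2, where the median was −0.68. HHIP did not pass without any 1 AD library or without margin library 4. The camera adjusted p was 0.000246, and 0.644 with an estimated correlation. Here too the design confounds disease with donors, body site and the surgical origin of the margin skin.

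Among dermal genes DPT, which encodes a matrix protein, fell by 2.15 (SE 0.45), from 76.0 ± 18.9 to 17.2 ± 8.69 CPM, and passed without AD library 3 or margin library 1 but in no other such fit. It was 1 of 20 fibroblast and matrix genes to fall, with 2 over the list alone. That list's median was −0.81 overall and 0.36 without margin library 1, and its camera adjusted p was 0.0319, or 0.811 with an estimated correlation. ADAMTS4 fell by 2.34 (SE 0.41) and did not pass without AD library 3 or 4, or margin library 2 or 4. It was the only one of 13 remodelling genes to pass (median 0.23). CLDN5 fell by 1.58 (SE 0.28), 1 of 18 endothelial genes to pass (median −0.27), but did not pass without AD library 2, 3 or 4, or margin library 4. NOTCH3 changed by 0.97 (SE 0.27, adjusted p = 0.0751) in the smooth muscle and pericyte list, in which 1 rose and 1 fell over the list alone of 13 (median −0.52). SCN7A, of 11 nerve genes (median −0.14), fell by 1.20 (SE 0.27) and passed without margin library 3 but in no other such fit.

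MITF (ENSG00000187098, chromosome 3, 69739435 to 69968337), a regulator of pigment cells, fell by 1.35 (SE 0.17, adjusted p = 0.0141), from 106 ± 17.2 to 41.5 ± 5.66 CPM. The other 10 tested melanocyte genes were positive, among them PMEL (1.33) and TYR (1.16), and the list's median was 0.80 (camera adjusted p = 0.05001, just short of a call). None of those 10 passed over all genes and 1 rose over the list alone. The list's median was 0.53 without AD library 3 and 0.98 without AD library 2. Camera called this list in 3 of the 8 fits with 1 library left out. The remaining genes with the largest rise were SLC5A5, a sodium and iodide transporter (5.58, SE 1.01), SH2D5 (4.17, SE 0.84), AKR1B15 (3.44, SE 0.67), whose near copy AKR1B10 makes its count uncertain, and CA2 (3.33, SE 0.48). CA2 passed in each fit with 1 library left out except without margin library 4. SLC5A5 passed without AD library 3 and was below the filter without AD library 1 or 2, while SH2D5 passed without AD library 1 and AKR1B15 without AD library 1 or margin library 3. Circadian clock genes had a median of −0.07, with PER1 at −1.33 (SE 0.41, adjusted p = 0.0931). Mitochondrially encoded genes had a median of 0.36, with MT-CO1 at 0.36 (SE 0.38), and no member of these lists passed. The mitochondrial median was 0.16 without AD library 3 and 0.57 without AD library 1. Camera called the mitochondrial list in 3 of the 8 fits with 1 library left out. The 4 red blood cell genes tested had a median of −0.50, with HBB at −0.996 (SE 1.41). This median was −3.14 without AD library 4 and −0.19 without AD library 2. HBB was at 56.2 CPM in AD library 4 and at 0.79 to 1.76 in the other AD libraries.

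**Figure D3:**
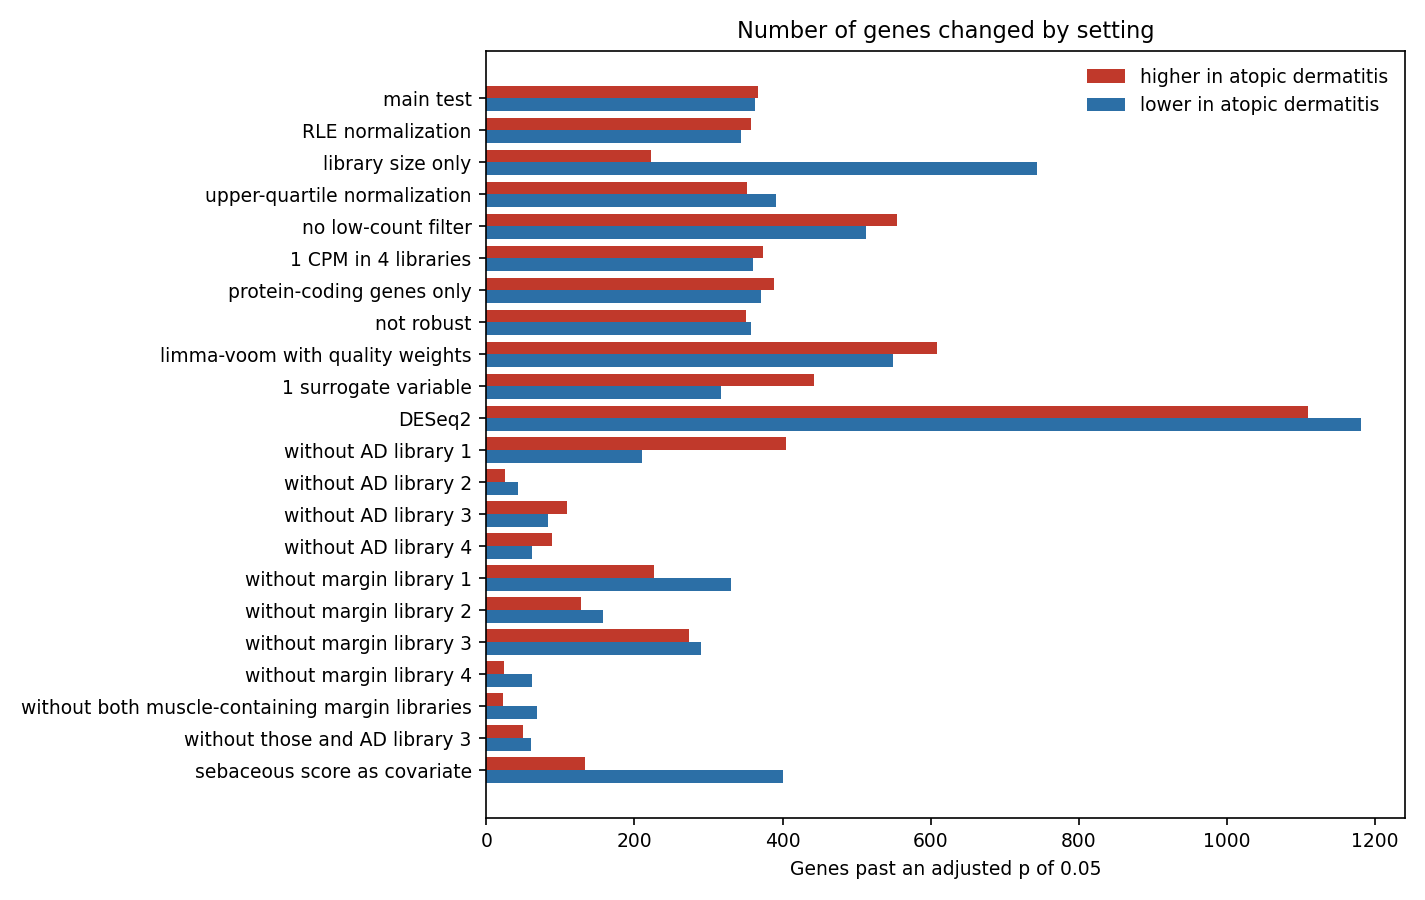
Number of genes higher (red) and lower (blue) in AD past an adjusted p of 0.05 in the main test and in each alternative, on a linear axis. Among the planned settings the fewest genes, 25 higher and 43 lower, are called without AD library 2, and the most, 1110 and 1181, with DESeq2.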

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

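All tests of explanations given here were chosen after the results were seen. In each group of 4 libraries a library was noted when it lay far from the other three. This held in 18 of 200 groups, where chance gives about 10, so most of these lie within what chance gives. Values are log2 CPM, or the mean log2 CPM of a list.

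In AD library 3 the Langerhans and dendritic cell list scored 1.399, against 3.36 to 3.71 in the other AD libraries. In the same library DPT was at 2.17 (4.37 to 4.55 in the others), HOXD8 at 1.78 (2.25 to 2.33), KRT6B at 8.54 (10.66 to 10.90) and KRT6C at 7.23 (10.08 to 10.50). FADS2, a sebaceous gene, was at 9.83 (4.36 to 5.03).

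In AD library 1 the basal keratinocyte list scored 8.60 (9.01 to 9.06 in the others), and KRTAP7-1 was at −2.02 with 1 count. In AD library 2 KRTAP19-3 was at −1.61 and KRTAP19-5 at −2.01, where the others had no counts. In AD library 4 CA2 was at 9.12 (7.29 to 7.51) and the red blood cell list scored 3.33 (−0.23 to 0.23).

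In margin library 2 the terminal differentiation list scored 5.87 (7.46 to 7.77), the red blood cell list 0.98 (2.67 to 2.97) and CD36 was at 6.05 (8.27 to 8.43). In margin library 3 S100A7 was at 10.92 (6.33 to 6.97), SLC5A5 at −1.42 (−0.72 to −0.58) and the circadian clock list scored 5.41 (5.97 to 6.04). No explanation was tested for the values in AD libraries 1, 2 and 4 and in margin libraries 2 and 3.

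AD library 3 was the lowest of its group in 5 of 7 leukocyte lists. Lower depth does not explain this, since its 12.57 M counts exceed the 10.04 M of AD library 4. Dilution of leukocytes by other tissue may contribute: 5 lists of other dermal cells deviated by −0.35 on average and the 7 leukocyte lists by −1.33. AD library 3 was also the lowest of its group in 3 of those 5 lists. An exact permutation test over the lists gave a p of 0.0556. Its units are lists within that library, which are not independent, so it cannot decide and dilution stays open. A first version of this test, with 11 other lists that included epidermal, gland, hair and muscle genes, gave an exact permutation p of 0.00239 and was replaced because those tissues could be the diluting ones. A true difference between donors was not tested.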

How the results depend on the processing

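The settings without margin libraries 3 and 4, without those and AD library 3, and with the sebaceous score as a covariate were chosen after the data were seen. All 39 named genes past the threshold kept their sign in every setting, 20 kept the call in every planned setting with all libraries that tested them, and 4 in every fit with 1 library left out that tested them. Of 730 called genes, 688 were shared with RLE, 673 with upper-quartile factors, 582 with library size alone, 684 with limma-voom and 729 with DESeq2.

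Genes higher and lower numbered 223 and 744 with library size alone, whose median shift of −0.20 moves genes to the lower side. Without a filter 555 were higher. Limma-voom gave 609 and 549, and DESeq2 1110 and 1181. With each library left out in turn, 24 to 405 genes were higher and 43 to 330 lower, 6 to 11 lists higher and 5 to 9 lower. Without margin libraries 3 and 4, 23 and 68 were called, without those and AD library 3, 50 and 60, and with the sebaceous score 133 and 401. Fewer samples lower the power of the fits with libraries left out. Protein-coding genes alone gave 5 lists higher. With an estimated correlation 0 lists were higher and 0 lower, and the directional test of fry gave 0 and 0. For the 16 lists called at the preset correlation, the adjusted p was 0.644 to 0.811 with an estimated correlation and 0.125 to 0.574 with fry, so no directional list call stands without the preset. The mixed test of fry, for change in either direction, passed for 9 of these 16 lists. Over all 33 lists tested it passed for 16, so it also passed for lists that camera did not call.

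These values changed sign; the cause was not tested except where stated. With library size alone KIT was −0.077, LOR −0.026, the interferon-gamma list −0.12 and the T cell list −0.15, as its shift gives. With limma-voom IGKC was −1.18, gene LOR −0.066, the itch list 0.0027 and the natural killer list 0.44. With 1 surrogate variable the natural killer list was 0.18 and the clock list 0.020, and without a filter the natural killer list was 0.027 and the interferon-gamma list −0.014.

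Without margin libraries 3 and 4 CD36 was 0.29, FADS2 0.13, KIT −0.014, the interferon-gamma list −0.45, the HOX list −0.085, T cell −0.12, adipocyte 0.060, skeletal muscle 0.20 and sweat gland −0.018. Without those and AD library 3 CD36 was 0.57, KIT −0.16, the interferon-gamma list −0.24, adipocyte 0.21, skeletal muscle 0.42 and sweat gland −0.036. With the sebaceous score FADS2 was 0.28, FLG −0.016, dendritic cell −0.44, T cell −0.71, interferon-gamma −1.03, remodelling −0.050, sebaceous gland 0.18 and type I interferon −0.14. FADS2 and the sebaceous list change there by construction, as the covariate holds them.

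With 1 library left out the values ran from −0.55 to 0.047 for CD36, −0.39 to 0.49 for FLG, −0.029 to 0.25 for KIT and −0.35 to 0.46 for LOR. For lists they ran from −0.49 to 0.0092 (nerve), −0.18 to 0.41 (T cell), −0.41 to 0.15 (endothelial), −1.03 to 0.36 (fibroblast), −0.49 to 0.16 (immediate early), −0.37 to 0.42 (interferon-gamma), −0.24 to 1.64 (interleukin-17 and interleukin-22) and −0.38 to 0.28 (natural killer). The count filter left 98 list members with at least 1 count untested, of which IL22 and OSM passed without it and IL13 and CCL26 did not. Members with 0 counts in all libraries, CCL18 and IL31 among them, were tested in neither setting. At this size 8.57% of 2-fold changes were recovered in simulated data, which covered genes above the filter only.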

Other observations

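All tests of explanations, the splits of the libraries, the list score tests and the family tests reported here were chosen, or written down, after the results were seen. Of the 35 splits of the 8 libraries, 1 gave as many as 730 genes, the real one, and the highest of the other splits gave 23. Chance alone would rank the real split first in 1 of 35 cases, the smallest share these splits can give. The other splits mix AD and margin libraries, which lowers their counts if the groups differ. The gap from 23 to 730 is therefore no measure of chance. For the 16 lists called by camera, 18 of 35 splits gave as many, with up to 23 in another split, so chance cannot be excluded. An exact permutation test of each of the 35 list scores gave its smallest possible p, 0.0286, for proliferation and Hedgehog, and an adjusted p of 0.333 for both.

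Some keratinocyte genes rose in AD, 4 of 24 on the activated list, 4 of 14 on the basal list and 6 of 33 on the differentiation list, and with an estimated correlation the adjusted p of these lists was 0.644 to 0.776. Tissue in margin libraries 3 and 4 does not explain the positive median of the activated list, which was 3.22 without them and 2.04 with them, although with these 2 left out none of its members passed over all genes and 14 passed over the list alone. A larger share of epidermis in the AD biopsies may explain part of it: the activated minus the basal score was −1.20 ± 1.301 in AD and −3.11 ± 1.44 in margin skin (mean ± SD, n = 4 each), an exact permutation p of 0.114, which leaves it open. A response of keratinocytes in AD is also open, and the design confounds disease with donors, body site and the surgical origin of the margin skin.

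Hair follicle, sebaceous gland, fat and muscle lists had negative medians in AD, with no member past the threshold over all genes. The sweat gland list had a median of 0.43. Its median ran from 0.23 to 1.05 with 1 library left out and was negative without margin libraries 3 and 4. Without margin libraries 3 and 4 the median was 0.20 for skeletal muscle, 0.060 for adipocyte and −0.24 for sebaceous gland genes. These 2 libraries were left out because they scored highest, so the differences had to shrink, and this fit does not test their source. AD library 3, with a sebaceous score of 5.51 against 1.72 to 2.42 in the other AD libraries, also narrows the sebaceous difference. Other tissue in margin libraries 3 and 4 remains a candidate source. In them the muscle gene TTN had 24060 and 2614 CPM, against 213 to 299 in the other 6. For hair follicle genes the median was −3.41 without them, so this tissue does not account for the hair genes. A different body site remains a candidate explanation for the hair genes: 1 margin library had a HOX score at or above the lowest in AD together with a hair score above AD, too few to decide.

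Gene families with at least 8 tested protein-coding members, 242 in all, were searched for an excess of calls with a one-sided Fisher exact test. Keratin-associated proteins had 15 of 22 members lower (adjusted p = 4.72e-18) and keratins 9 of 43 higher (adjusted p = 0.000134). Yet 26 of the 43 keratins had a negative change, and the family median was −1.24. The keratins called lower were 3: KRT15, KRT26 and KRT38. The count of keratins called higher was 2 without AD library 2 or margin library 4, and 4 without AD library 4. It was 5 without margin library 2 and 6 to 8 without each other library. The count of keratin-associated proteins was 1 without AD library 2. ADAMTS genes had 4 of 17 lower, ADAMTS1, ADAMTS4, ADAMTS9 and ADAMTS18, with an adjusted p of 0.0635. A first version over genes of every type, with 290 families, gave an adjusted p of 0.00546 for ADAMTS and counted an antisense RNA among its members, so the family is not reported as changed. Members of a family are not independent, and neighbouring copies share reads.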
